A study of Mus musculus with 60 samples.

How the data were processed

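Gene expression was measured by bulk 3′ digital gene expression RNA sequencing in 3 tissues of C57BL/6JN mice: subcutaneous white adipose tissue (scWAT), visceral white adipose tissue (vWAT) and triceps muscle. Per the labels, each tissue held 4 groups of 5 mice, given chow with 10% of energy from fat or a high-fat diet (HFD) with 60% for 6 weeks. Within each diet the mice were sedentary or ran voluntarily on a wheel for the last 3 weeks. Tissues were taken after a fast of 6 hours and a wash-out of 24 hours with locked wheels, at an age of 12 weeks. The animal codes in the sample titles show that the same 20 animals gave all 60 libraries.

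Per the labels' protocols, RNA was reverse transcribed with template switching, cDNA from 12 wells with well identifiers was pooled, and libraries were made by Nextera tagmentation and read single-end on a HiSeq 2000. Quantification used Salmon 0.14.2 with the mm10 build, per the submitters' processing notes. The deposited table gave, per the file headers, 1 estimated count column per library, which the authors had rounded to whole numbers. It also gave a log2 column per library, which the authors made as the log2 of CPM (counts scaled to a library total of 1e+06) plus 1; turned back, each such column summed to that total. The counts were used for every test, and the deposited log2 values only to check the unit. The strand setting and any use of molecular identifiers for removing PCR copies are not given in the sources used here. The limit given for a count of 0 therefore covers counting error only, whereas standard errors come from fits over mice.

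The table held 54352 genes, of which 26846 had no count in any library. Symbols were those of the table; 259 were blank and 108 were shared by more than 1 gene, so genes were followed by their Ensembl identifiers. Coordinates come from GENCODE vM21, on the same mm10 (GRCm38) assembly. With 3′ tags, reads are divided among paralogs and pseudogenes by estimation, so single members of families such as Saa, H2, Myh, Scd, Hba and the immunoglobulin genes carry an uncertainty that the tables do not show. The largest such case was Gm29216, a nuclear copy of mitochondrial sequence, with 679470 counts over all libraries.

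Total estimated counts per library ranged from 505336 to 744581, with a median of 666522.5. A count of 0 allows up to 3 counts, which is 4.17 to 5.94 CPM in scWAT, 4.35 to 5.17 in vWAT and 4.03 to 4.61 in triceps. CPM values in the text are the mean ± SD over the 5 mice of a group, on total counts.

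Each tissue was fitted on its own with edgeR 4.0.16, using TMM normalisation, filterByExpr by group and the robust quasi-likelihood fit, in R 4.3.3. This left 7069 genes in scWAT, 6990 in vWAT and 4410 in triceps. Contrasts were the HFD effect in sedentary mice, the training effect on chow, the training effect on HFD, the HFD effect in trained mice and the diet by training interaction. All adjusted p values for genes are from edgeR's two-sided quasi-likelihood test with the Benjamini-Hochberg correction over the genes tested in that tissue and contrast, and a gene was called below 0.05. Log2 fold changes are those of edgeR's fit, and each standard error (SE) was computed from the change and its test statistic. The log2 CPM values behind the list tests had a prior count of 2. Log2 fold changes are on the TMM scale, so they differ from the ratio of the CPM means on total counts. From total counts to TMM, log2 fold changes moved by −0.18 in scWAT and −0.20 in vWAT for diet in sedentary mice and by −0.27 and −0.17 in trained mice. For training they moved by 0.12 on chow and 0.04 on HFD in scWAT, 0.03 and 0.06 in vWAT, and 0.13 and 0.19 in triceps. Changes are given relative to that scale, on which the median of all tested genes lay between −0.05 and 0.02 in every contrast. The difference between both fat depots in each effect was fitted on their joint counts with the animal as a block. Libraries of different tissues were joined only by the animal code, and replicate numbers within a tissue were treated as unpaired.

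Before the data were examined, 38 gene lists and the rule for naming genes were fixed. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. The camera p values were adjusted over the lists tested in that contrast. Called members are also counted as adjusted over the list alone. Per tissue and main contrast, the rule names up to 6 genes higher and 6 lower with the lowest adjusted p among called genes with an absolute log2 fold change of at least 1 and a mean log2 CPM of at least 4. It adds up to 3 called members per list and a short set of watched genes whatever their test gave, and names all genes where 5 or fewer were called. For the interaction, the HFD effect in trained mice and the depot difference it names up to 5 genes. The rule gave 265 called values, of which 177 kept their call in every fit that left out 1 library. The examples in the text were taken from those 177, and where another is given, that is stated.

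Fits under other settings used DESeq2 1.42.0, limma voom, the relative log expression (RLE) normalisation, no filter beyond at least 1 count, the non-robust fit, the replicate number as a block, only the groups compared, and leaving out each library in turn. Added after seeing the data were the library run as a factor, fits within runs, fits without 6 scWAT libraries, and scWAT marker scores as covariates. Runs were defined as 12 consecutive library codes in the file headers. The lists of organ markers behind these runs were written after such transcripts had been seen in some libraries, and the border between runs was placed where those lists differed most.

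The pipeline was tested on simulated data with 200 changed genes. At a log2 change of 1 it recovered 45.3% of changed genes in scWAT, 52.5% in vWAT and 70.7% in triceps, and at a change of 2 it recovered 90.0%, 96.9% and 96.9%. False calls were 3.1%, 3.3% and 3.1% of the calls. For the depot difference a change of 2 was recovered for 74% of changed genes, with 5.3% false calls. The simulated genes varied independently and held no library runs or other tissue, so these rates need not hold for the real libraries. Counts of called genes were set against 100 random splits of the same libraries, and 30 splits of animals for the depot difference. The share of genes with opposite changes was set against 20 simulated sets and 20 splits in which no group was shared by both contrasts.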

Results

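The data set asked how 6 weeks of high-fat feeding and 3 weeks of wheel running changed gene expression in a pair of fat depots and in a muscle of the same mice. It held 60 libraries from 20 mice, with 5 mice in each of 12 groups of tissue, diet and activity. Total estimated counts per library ran from 505336 to 720220 in subcutaneous fat (median 636333), from 580173 to 689060 in visceral fat (median 642556.5) and from 651030 to 744581 in triceps (median 722315.5). Mitochondrial ribosomal RNA took 5.54% of all counts. No pair among the 120 pairs of libraries within a group was identical.

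Some libraries held transcripts of organs that were not sampled, and some of these followed the order of the library codes. In vWAT, the 5 chow libraries of 1 run held 707 to 916 reads of heart genes, against at most 12 in the other vWAT libraries, and 3 HFD libraries of another run held 264 to 397 reads of intestinal genes, against at most 21. In triceps, intestinal reads were at 228 to 276 in the 5 chow libraries of 1 run and at most 4 elsewhere, and brain reads were at 60 to 78 in the 3 HFD libraries of another run and at most 4 elsewhere. Within vWAT and within triceps each of these runs held 1 diet only, and the remaining run of 12 libraries in each tissue held all 4 groups. The 5 chow triceps libraries with intestinal reads shared their run with the 3 HFD vWAT libraries. The highest heart share in vWAT was 0.148% of a library. Heart genes in triceps did not follow the runs, at 67 to 1365 reads (up to 0.185%) in the run with all 4 groups and up to 585 outside it, and brain reads in scWAT overlapped between runs. Liver reads followed the runs in scWAT, with 510 to 784 in the 9 libraries of 1 run and at most 209 in the other 11. In triceps they were at 67 to 88 in the run with intestinal reads, at 37 to 67 in the run with brain reads and at most 4 in the run of 12. In vWAT they did not follow the runs, with 842 to 2341 in the 3 libraries of the run with intestinal reads but up to 4438 outside it. The 4438 were in HFD sedentary replicate 3, which had 664156 counts in total. Liver reads ranged from 95 to 4438 in HFD and from 87 to 582 in chow libraries of vWAT. The 3 vWAT libraries of the run with intestinal reads also held 1908 to 2975 reads of skeletal muscle genes, against 83 to 465 in the other 17. In scWAT, 6 libraries, all from chow mice, held 294 to 752 reads of B cell genes without Ighm, against at most 31 in the other 14. The same 6 held 403 to 1108 reads of the lymph node stroma genes Ccl21a, Ccl19 and Cxcl13, against at most 19. By Fisher's exact test, two-sided, 6 of 10 chow against 0 of 10 HFD libraries gave p = 0.0108. Reads of skeletal muscle genes in scWAT ranged from 131 to 72603 per library, with the highest in chow trained replicate 3, which had 688566 counts in total. Counts of called genes within runs and without these libraries are given with the comparisons they bear on.

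**Figure D1:**
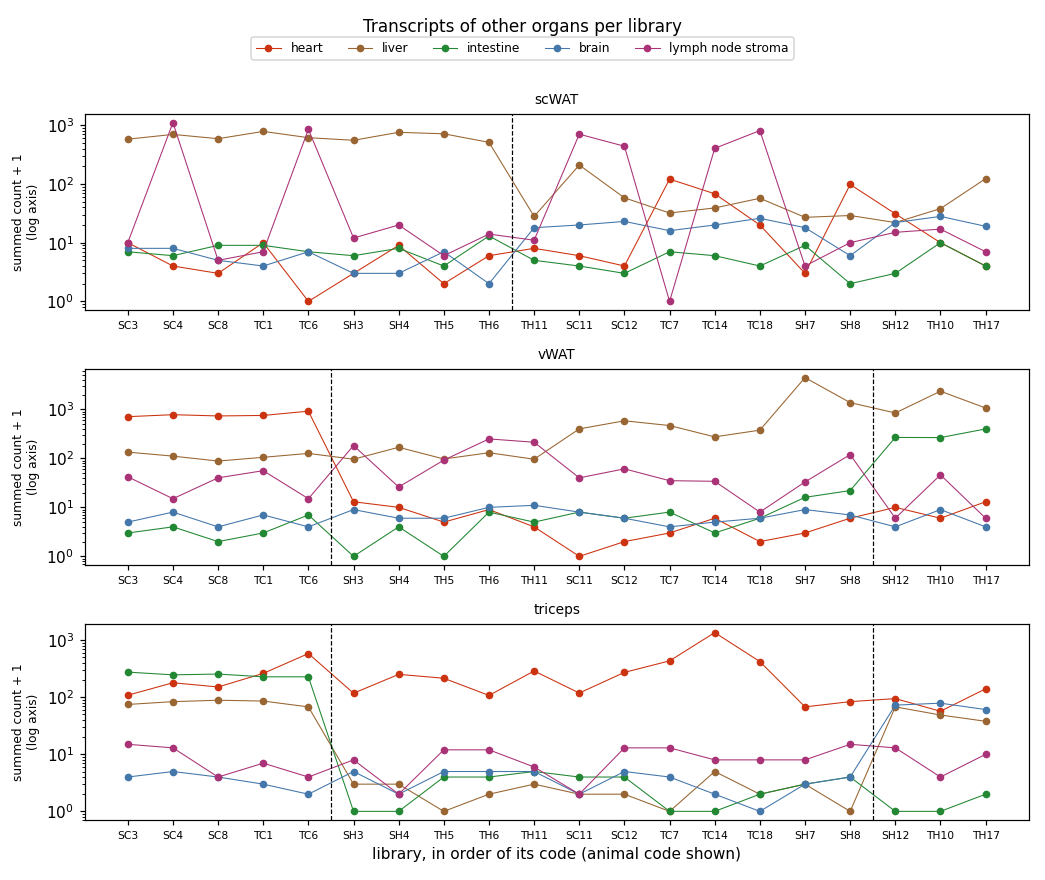
Summed count plus 1 of 5 organ marker lists (log axis, 1 colour each) in every library, with libraries in the order of their codes and dashed lines at the borders between runs. Heart reads stand at 707 to 916 in 5 vWAT libraries, and lymph node stroma reads at 403 to 1108 in 6 chow scWAT libraries.

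The first comparison asked what the high-fat diet did to subcutaneous fat of sedentary mice. The enzymes that make fatty acids from glucose fell. Acaca, acetyl-CoA carboxylase (ENSMUSG00000020532, mm10 chromosome 11, 84129672 to 84401651), fell by 3.13 on the log2 scale (SE 0.31, adjusted p = 1.46e-06), from 560 ± 249 to 75.2 ± 18.6 CPM (SD, n = 5). Fasn, fatty acid synthase, fell by 3.22 (SE 0.34, adjusted p = 5.2e-06), from 1170 ± 462 to 146 ± 38.5 CPM, and Scd1, the desaturase that makes oleate, fell by 1.58 (SE 0.29, adjusted p = 0.00144). Genes of growing adipocytes rose. The satiety hormone gene Lep (chromosome 6, 29060220 to 29073877) rose by 2.81 (SE 0.36, adjusted p = 4.73e-05), from 210 ± 123 to 1730 ± 713 CPM, and Mest, an imprinted gene tied to adipocyte size (chromosome 6, 30723547 to 30748465), rose by 3.28 (SE 0.38, adjusted p = 1.69e-05), from 23.3 ± 16.2 to 265 ± 98 CPM. The matrix genes Efemp1 (chromosome 11, 28853204 to 28926743; 2.17, SE 0.22) and Thbs1, which activates TGF-beta (2.67, SE 0.32), also rose, as did the haemoglobin scavenger Hp (2.20, SE 0.27).

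Of the 7069 genes tested in this comparison, 449 were called, 251 higher and 198 lower, and 1490 had an unadjusted p under 0.05. The fatty acid and triglyceride synthesis list had 15 of 22 members lower (16 adjusted over the list alone, median −1.39, camera adjusted p = 5.47e-20, 0.0507 with an estimated correlation). All 6 adipose expansion genes were higher (6 adjusted over the list alone, median 2.48, camera adjusted p = 2.32e-11, 0.0408 with an estimated correlation). Respiratory chain genes of the nucleus had 20 of 74 lower (45 adjusted over the list alone, median −0.48, camera adjusted p = 3.26e-20, 0.248 with an estimated correlation), among them Ndufa1 of complex I at −0.87 and Uqcr10 of complex III at −0.78. Of the 26 fatty acid oxidation genes, 6 were lower and none higher (10 lower and 1 higher adjusted over the list alone, median −0.51), including Cpt2 (−0.94, SE 0.19) and Hadha (−0.99, SE 0.23). The extracellular matrix list had 9 of 40 higher (26 adjusted over the list alone, median 0.69, camera adjusted p = 7.15e-18, 0.0522 with an estimated correlation). Acute-phase and complement genes had 6 of 12 higher (8 higher and 1 lower adjusted over the list alone, median 0.84, camera adjusted p = 2.82e-06, 0.035 with an estimated correlation) with Cfb, complement factor B, at 1.08 (SE 0.16, adjusted p = 0.000152). Macrophage markers had 2 of 16 higher (7 adjusted over the list alone, median 0.73, camera adjusted p = 0.000285, 0.344 with an estimated correlation). Itgax, a marker of inflammatory macrophages, was too low to test, at 2.11 ± 2.24 and 4.55 ± 0.948 CPM.

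Mitochondrially encoded transcripts were looked at in this comparison only after their values had been seen. The cytochrome oxidase gene mt-Co3 fell by 1.10 (SE 0.22, adjusted p = 0.00282), and 9 of the 13 mitochondrially encoded protein genes were called lower. Over the 16 mitochondrial genes tested the median was −0.92 (SD 0.19 across genes), and −0.92 without the 6 lymph node libraries, where 6 of 13 protein genes were lower. The share of counts from mitochondrial genes was 15.45 to 21.52% in chow sedentary and 8.33 to 14.6% in HFD sedentary libraries. Within the runs of 9 and 11 libraries the medians were −1.18 and −0.89. There mt-Co3 was at −1.20 and −0.99 but was not called (adjusted p = 0.241 and 0.0525). The sedentary libraries were 3 chow and 2 HFD in the run of 9, and 2 chow and 3 HFD in the run of 11.

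A few heat-producing genes of beige fat were lower in the HFD group, with wide spreads. Elovl3, an elongase of cold-exposed fat, fell by 4.97 (SE 0.97, adjusted p = 0.00251) and the lipid droplet gene Cidea fell by 3.61 (SE 0.72, adjusted p = 0.00619), and 3 of 11 thermogenic genes were lower (9 adjusted over the list alone, median −1.57, camera adjusted p = 1.94e-07, 0.0649 with an estimated correlation). The uncoupling protein gene Ucp1 (chromosome 8, 83290352 to 83298452) did not pass (−4.99, SE 1.55, adjusted p = 0.0652), at 218 ± 229 and 7.55 ± 3.48 CPM. Neither did Adipoq (0.32, adjusted p = 0.42), Col1a1 (0.82, adjusted p = 0.118) or the coactivator Ppargc1a (0.11, adjusted p = 0.942).

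Lists of lymphocyte genes were lower with the diet in this depot at camera's preset correlation, but did not pass with an estimated one. B cell genes had 4 of 10 lower (9 lower and 1 higher adjusted over the list alone, median −4.55, camera adjusted p = 0.002, 0.462 with an estimated correlation) and T and NK cell genes 1 of 10 lower (10 adjusted over the list alone, median −3.56, camera adjusted p = 0.000601, 0.449 with an estimated correlation), and the 6 libraries with lymph node transcripts were all from chow mice. Among their called genes, Cd79a, Cd79b and Fcer2a each lost the call in 8 of 10 fits that left out 1 library, and Cd4 in 6. None of the 15 skeletal muscle markers was called. Without those 6 libraries 139 genes were called, 45 higher and 94 lower, of which 104 were among the 449. The fatty acid synthesis median was then −1.91, adipose expansion 1.69, the respiratory chain −0.55 and the matrix 0.34. Acaca, Fasn, Scd1, Lep, Mest, Efemp1, Thbs1, Hp, Ndufa1, Uqcr10, Cpt2, Hadha, Cfb and Elovl3 kept their calls in that fit, while Cidea at −3.12 (adjusted p = 0.147), Cd34 at 0.98 (adjusted p = 0.107) and Acta2 at 0.97 (adjusted p = 0.0964) did not. Adding the library run as a factor gave 586 genes. The run of 11 libraries alone called 267 and the run of 9 libraries called 0. Leaving out chow sedentary replicate 4 gave 243 genes and leaving out HFD sedentary replicate 5 gave 291.

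The second comparison asked what wheel running did to subcutaneous fat of chow-fed mice. No gene was called by edgeR, with 376 genes at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by voom. Lep changed by −0.94 (SE 0.35, adjusted p = 0.757), Fasn by 0.28 (SE 0.31, adjusted p = 0.998), Scd1 by −0.32 (SE 0.28, adjusted p = 0.987) and Ucp1 by 0.05 (SE 1.15). As a set, circadian clock genes were higher with no member called (3 adjusted over the list alone, median 0.70, camera adjusted p = 0.000381, 0.2 with an estimated correlation). Skeletal muscle markers had a median of 2.57 in this comparison. The run as a factor gave 1 gene, covariates for B cell and muscle scores gave 9, and each run alone and the fit without the 6 lymph node libraries gave 0. Leaving out chow sedentary replicate 2 gave 1 gene and leaving out chow trained replicate 3 gave 5.

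The third comparison asked what running did to subcutaneous fat under the high-fat diet. The genes that fell included Thbs1 and Ccl2, and clock-controlled genes rose. Thbs1 (chromosome 2, 118111876 to 118127133) fell by 2.27 (SE 0.30, adjusted p = 0.000363), from 83.9 ± 44.6 to 16.6 ± 2.76 CPM (SD, n = 5), and Ccl2, which draws in monocytes, fell by 2.76 (SE 0.41, adjusted p = 0.00128), from 39.5 ± 13.7 to 5.53 ± 3.07 CPM. The acute-phase gene Saa3 fell by 3.40 (SE 0.56) and the cell cycle inhibitor Cdkn1a fell by 2.08 (SE 0.37), both with an adjusted p of 0.0051. Dbp, a transcription factor driven by the clock (chromosome 7, 45705088 to 45710203), rose by 2.90 (SE 0.49, adjusted p = 0.0051), from 5.54 ± 2.88 to 41.4 ± 12.4 CPM, with Per3 at 1.57 (SE 0.29) and Tef at 1.44 (SE 0.28). Cpt2, which brings fatty acids into mitochondrial oxidation (chromosome 4, 107903981 to 107923610), rose by 1.23 (SE 0.19, adjusted p = 0.00188), from 65.7 ± 8.8 to 149 ± 34.8 CPM. The lactate receptor Hcar1 (1.43, SE 0.23), the vitamin carrier Slc5a6 (2.30, SE 0.40) and the insulin signalling kinase Akt2 (1.05, SE 0.20) rose as well.

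In this comparison 71 genes were called, 50 higher and 21 lower, with 785 at an unadjusted p under 0.05. The clock list had 5 of 10 higher (6 adjusted over the list alone, median 1.21, camera adjusted p = 5.53e-07, 0.0267 with an estimated correlation). The insulin signalling list had 1 of 9 higher (3 adjusted over the list alone, median 0.53, camera adjusted p = 0.000104, 0.0403 with an estimated correlation). Fatty acid synthesis had 2 of 22 higher (9 adjusted over the list alone, median 0.57, camera adjusted p = 4.55e-08, 0.194 with an estimated correlation), and macrophage markers had 0 of 16 called (median −0.52, camera adjusted p = 6.3e-06, 0.204 with an estimated correlation). Acute-phase and complement genes had 3 of 12 lower (5 adjusted over the list alone, median −0.21, camera adjusted p = 0.00385, 0.155 with an estimated correlation), and matrix genes 1 of 40 lower (1 adjusted over the list alone, median −0.31, camera adjusted p = 1.4e-06, 0.236 with an estimated correlation). Skeletal muscle markers were 15 of 15 lower when adjusted over the list alone, with none called over all genes (median −4.60, camera adjusted p = 1.14e-07, 0.236 with an estimated correlation). These members are not separate evidence, since all follow the muscle held in a piece of fat. Their summed reads overlapped, at 349 to 47451 in HFD sedentary libraries, highest in replicate 4, and at 166 to 1355 in HFD trained libraries. Lep fell by 1.58 (SE 0.34, adjusted p = 0.0229), to 558 ± 162 CPM, but lost its call without HFD sedentary replicate 1 or 5 or HFD trained replicate 2, 3 or 4, with adjusted p values from 0.0542 to 0.0847. Fasn (0.93, SE 0.32, adjusted p = 0.238) and Ucp1 (4.15, SE 1.54, adjusted p = 0.286) did not pass.

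The count of 71 was sensitive to 7 of the 10 libraries. It fell to 42, 45, 45 and 28 without HFD sedentary replicates 1, 2, 4 and 5, and to 42, 36 and 37 without HFD trained replicates 2, 3 and 4. Within the run of 11 libraries 22 genes were called, and within the run of 9 libraries none. The run as a factor gave 90 genes, B cell and muscle scores as covariates gave 91, and leaving out the 6 lymph node libraries gave 109, of which 66 were among the 71. DESeq2 called 136 genes and voom 109.

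In trained mice the diet contrast called 365 genes in subcutaneous fat, 223 higher and 142 lower. Of them 191 were also called in sedentary mice, all 191 in the same direction. The lowest adjusted p values were those of the interferon-induced gene Ifi27l2a (2.18, SE 0.20) and the nicotinamide methyltransferase gene Nnmt (1.79, SE 0.17), both 2.53e-07, followed by Anxa6 (1.28, SE 0.14), Mest (3.98, SE 0.43) and Sncg (1.76, SE 0.21). Fatty acid synthesis genes had 10 of 22 lower (12 adjusted over the list alone, median −0.84, adjusted p = 0.135 with an estimated correlation) and matrix genes 10 of 40 higher (23 adjusted over the list alone, median 0.70, adjusted p = 0.186 with an estimated correlation). B cell and muscle markers had medians of −5.20 and −5.73. Summed muscle reads were at 224 to 72603 in chow trained and at 166 to 1355 in HFD trained libraries. Without the 6 lymph node libraries 149 genes were called, of which 109 were among the 365. With the B cell and muscle covariates 183 were called, of which only 97 were among the 365. The count was 456 with the run as a factor, 0 in the run of 9 libraries and 235 in the run of 11. It was 610, 200, 234 and 217 without chow trained replicates 1, 2, 4 and 5, and 208, 222 and 210 without HFD trained replicates 1, 4 and 5. The interaction of diet and training had 0 genes by edgeR, with 438 at an unadjusted p under 0.05, 31 by DESeq2 and 0 by voom; without chow trained replicate 1 it had 1.

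**Figure D2:**
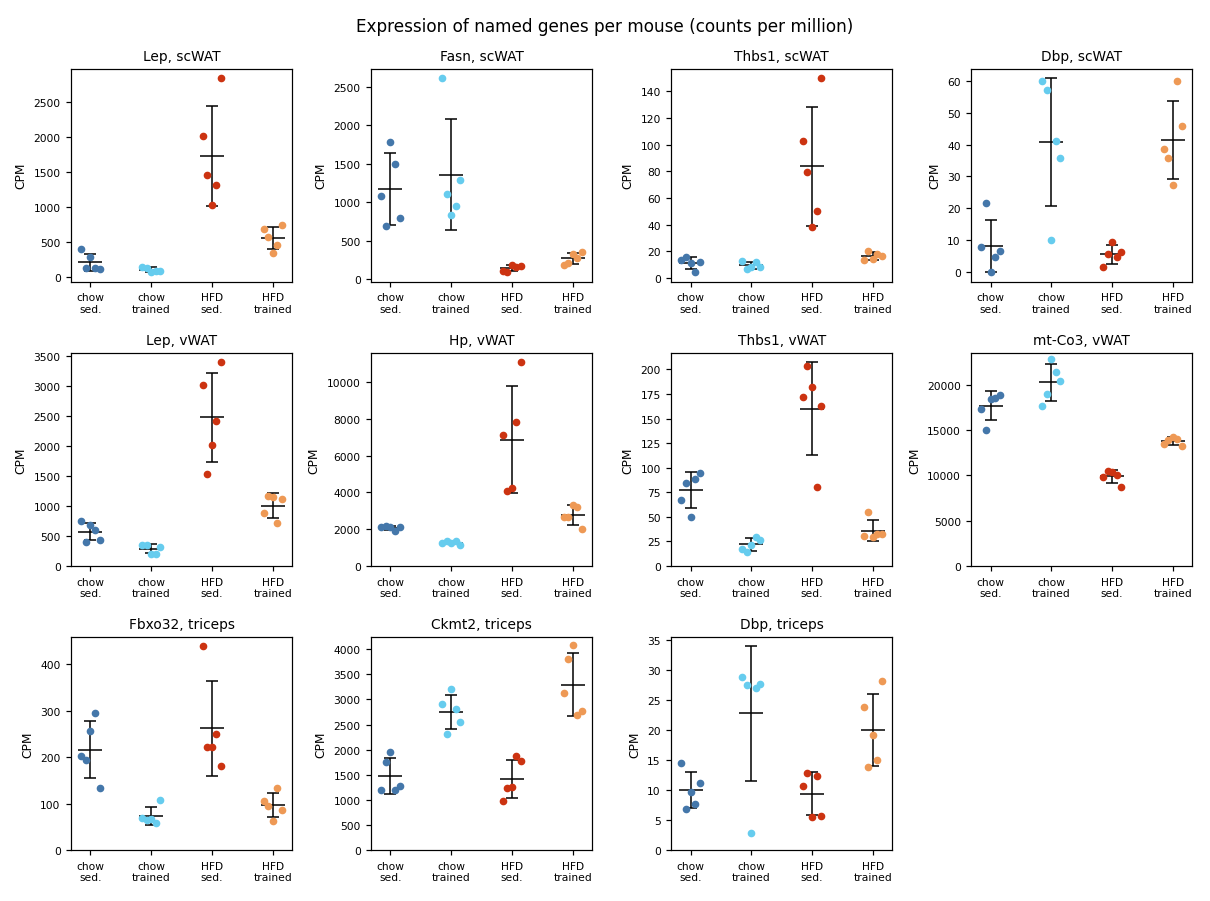
CPM of 11 gene and tissue pairs in each mouse, by diet and activity group, with points for mice and bars for the mean and SD of 5 mice. Lep stands highest in sedentary HFD mice of both depots. In the scWAT and triceps panels, Dbp is higher in all trained than in all sedentary HFD mice. On chow, most trained mice stand above all sedentary mice for Dbp in both panels.

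The same questions were asked of visceral fat. In sedentary mice the diet lowered the mitochondrially encoded transcripts together. The cytochrome oxidase gene mt-Co3 (mitochondrial genome, 8607 to 9390) fell by 1.04 (SE 0.11, adjusted p = 1.33e-07), from 17700 ± 1600 to 9900 ± 691 CPM (SD, n = 5), and mt-Atp6, mt-Nd3 and mt-Nd4l changed by −1.09 (SE 0.12), −1.22 (SE 0.13) and −1.39 (SE 0.17). Over the 16 mitochondrial genes tested, 15 were lower and 0 higher, with a median of −1.04 (SD 0.24 across genes). In the run that held all 4 groups, with 2 chow and 4 HFD sedentary mice, 13 of 17 were lower with a median of −1.01. Acaca fell by 2.74 (SE 0.31, adjusted p = 2.18e-05) and Fasn by 2.36 (SE 0.39, adjusted p = 0.00107), and Scd1 changed by −1.31 (SE 0.25). Lep rose by 1.91 (SE 0.24, adjusted p = 7.01e-05), from 573 ± 149 to 2480 ± 747 CPM, and the Wnt inhibitor Sfrp5 rose by 2.42 (SE 0.32, adjusted p = 1.09e-05).

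Named genes of immune cells and of the matrix were among those that rose in the same comparison. The lysosomal protease gene Ctss (chromosome 3, 95526786 to 95556403) rose by 2.52 (SE 0.47, adjusted p = 0.00265), from 75.1 ± 7 to 498 ± 442 CPM, and Cd74, the chaperone of MHC class II, rose by 1.40 (SE 0.23, adjusted p = 0.000143). Saa3 rose by 4.42 (SE 0.79, adjusted p = 0.00207). Macrophage elastase Mmp12 (4.03, SE 0.83) and the osteoclast-type proton pump gene Atp6v0d2 (5.07, SE 1.06) are markers of lipid-laden macrophages. Among matrix genes, Pcolce2, which helps to process collagen, rose by 2.36 (SE 0.26, adjusted p = 5.13e-07), Col6a1 by 1.11 (SE 0.19) and Postn by 0.91 (SE 0.15). The insulin-responsive glucose carrier Slc2a4 fell by 0.86 (SE 0.19, adjusted p = 0.00387) and the adipocyte hormone gene Retn fell by 1.19 (SE 0.24). Itgax was too low to test, at 2.54 ± 2.4 and 14.9 ± 8.05 CPM, Ucp1 had a count of 0 in every vWAT library, and Ppargc1a did not pass (−0.59, adjusted p = 0.566).

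Of 6990 genes tested, 564 were called, 274 higher and 290 lower, with 1390 at an unadjusted p under 0.05. The nuclear respiratory chain list had 56 of 74 lower (69 adjusted over the list alone, median −0.49, camera adjusted p = 2.57e-41, 0.0429 with an estimated correlation). Fatty acid synthesis had 13 of 22 lower (16 adjusted over the list alone, median −1.15, camera adjusted p = 4.58e-15, 0.0429 with an estimated correlation), and the TCA cycle 10 of 20 lower (16 adjusted over the list alone, median −0.48). Macrophage markers had 13 of 17 higher (15 adjusted over the list alone, median 1.32, camera adjusted p = 3.13e-13, 0.0429 with an estimated correlation). Lipid-associated macrophage genes had 6 of 8 higher (6 higher and 1 lower adjusted over the list alone, median 2.34, camera adjusted p = 1.17e-05, 0.0755 with an estimated correlation), and MHC class II genes 6 of 6 higher (median 1.10, camera adjusted p = 1.49e-08, 0.0429 with an estimated correlation). The matrix list had 10 of 40 higher (17 adjusted over the list alone, median 0.40, camera adjusted p = 6.82e-08, 0.0429 with an estimated correlation) and insulin signalling 1 of 9 lower (7 adjusted over the list alone, median −0.63, camera adjusted p = 1.25e-05, 0.0429 with an estimated correlation).

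A model with the library run as a factor called 294 genes, 150 higher and 144 lower, of which 229 were among the 564. The run that held all 4 groups alone called 87, of which 81 were shared. The medians with the run as a factor and within that run were −1.26 and −1.08 for fatty acid synthesis, −0.31 and −0.26 for the nuclear respiratory chain, 1.14 and 0.91 for macrophages, 1.73 and 1.77 for lipid-associated macrophages, and 0.94 and 0.88 for MHC class II. In the former, Saa3 at 3.53 (adjusted p = 0.0526), Mmp12 at 3.61 (adjusted p = 0.0733) and Atp6v0d2 at 3.78 (adjusted p = 0.0744) were no longer called. Within the single run Fasn at −2.14 (adjusted p = 0.119), Ctss at 1.90 (adjusted p = 0.197) and Slc2a4 at −0.73 (adjusted p = 0.205) were not called either, whereas mt-Co3, mt-Atp6, mt-Nd3, mt-Nd4l, Acaca, Scd1, Lep, Sfrp5, Cd74, Pcolce2, Col6a1, Postn and Retn were called in both. Leaving out HFD sedentary replicate 5 gave 355 genes.

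Training on chow called 41 genes in visceral fat, 19 higher and 22 lower, with 581 at an unadjusted p under 0.05. Wfdc21, a secreted protease inhibitor of inflamed tissue, fell by 1.30 (SE 0.15, adjusted p = 6.68e-06), from 424 ± 98 to 169 ± 22.8 CPM (SD, n = 5). Thbs1 fell by 1.77 (SE 0.25, adjusted p = 0.000162), the aggrecanase gene Adamts5 fell by 1.12 (SE 0.17) and the lipase inhibitor Angptl4 fell by 0.84 (SE 0.13), both with an adjusted p of 0.000244. Dbp rose by 2.55 (SE 0.39, adjusted p = 0.000293) and Gpam, which starts triglyceride synthesis, rose by 1.06 (SE 0.19, adjusted p = 0.00232). Lep changed by −0.98 (SE 0.24) and did not pass (adjusted p = 0.0917).

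The clock list had 4 of 8 higher in this comparison (5 higher and 1 lower adjusted over the list alone, median 1.25, camera adjusted p = 1.55e-07, 0.0416 with an estimated correlation). Matrix genes had 3 of 40 lower (6 adjusted over the list alone, median −0.33, camera adjusted p = 1.47e-10, 0.0416 with an estimated correlation) and fatty acid synthesis 2 of 22 higher (6 higher and 1 lower adjusted over the list alone, median 0.61, camera adjusted p = 3.86e-11, 0.0939 with an estimated correlation). Adjusting for the run gave 44 genes, and the single run alone gave 6, where clock genes had a median of 0.90 and Dbp was at 2.38 (adjusted p = 0.2). Wfdc21 and Adamts5 were called in both fits. The count was 20 and 21 without chow sedentary replicates 1 and 4, and 22 and 21 without chow trained replicates 2 and 4.

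Training on HFD called more genes in visceral fat. Thbs1 fell by 2.09 (SE 0.22, adjusted p = 8.58e-07), from 160 ± 47.3 to 35.8 ± 10.7 CPM (SD, n = 5), Wfdc21 fell by 1.10 (SE 0.15, adjusted p = 3.2e-05) and the leukocyte GTPase gene Rac2 fell by 1.58 (SE 0.23, adjusted p = 0.000136). Hp fell by 1.24 (SE 0.20, adjusted p = 0.00155), Saa3 fell by 3.65 (SE 0.72, adjusted p = 0.011) and Lep fell by 1.24 (SE 0.24, adjusted p = 0.0074), to 1010 ± 202 CPM. The clock outputs Tef and Dbp rose by 1.94 (SE 0.27, adjusted p = 6.85e-05) and 2.52 (SE 0.41, adjusted p = 0.000663). Nrg4, a growth factor that fat releases, rose by 1.38 (SE 0.24, adjusted p = 0.000946) and Gpat3, of triglyceride synthesis, rose by 1.52 (SE 0.26). Fasn (0.98, adjusted p = 0.209), Scd1 (0.72, adjusted p = 0.146) and Adipoq (0.34, adjusted p = 0.166) did not pass.

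In that comparison 216 genes were called, 85 higher and 131 lower, with 1030 at an unadjusted p under 0.05. The clock list had 6 of 8 higher (7 adjusted over the list alone, median 1.48, camera adjusted p = 6.81e-10, 0.0141 with an estimated correlation). Macrophage markers had 8 of 17 lower (15 adjusted over the list alone, median −1.16, camera adjusted p = 2.59e-16, 0.0321 with an estimated correlation), MHC class II genes 6 of 6 lower (median −0.89, camera adjusted p = 2.51e-09, 0.0383 with an estimated correlation) and matrix genes 10 of 40 lower (18 adjusted over the list alone, median −0.50, camera adjusted p = 3.3e-15, 0.0104 with an estimated correlation). Insulin signalling genes had 4 of 9 higher (8 adjusted over the list alone, median 0.68, camera adjusted p = 8.91e-09, 0.0143 with an estimated correlation). Lipid-associated macrophage genes had 0 of 8 called (7 lower adjusted over the list alone, median −1.73, camera adjusted p = 6.63e-06, 0.0877 with an estimated correlation). The nuclear respiratory chain had 3 of 74 higher (23 adjusted over the list alone, median 0.25, camera adjusted p = 2e-17, 0.186 with an estimated correlation).

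Adjusting for the run gave 334 genes, and the single run alone gave 66. Within that run the medians were 1.16 for the clock, −0.74 for macrophages, −0.67 for MHC class II, −0.48 for the matrix and 0.61 for insulin signalling. Thbs1, Wfdc21, Rac2, Hp, Lep, Tef, Dbp, Nrg4 and Gpat3 were called in both fits, and Saa3 within the single run was not (−2.93, adjusted p = 0.33). The count was 121, 340, 127 and 84 without HFD sedentary replicates 1, 2, 4 and 5, and 115 and 113 without HFD trained replicates 1 and 4.

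In trained mice the diet changed 183 genes in visceral fat, 84 higher and 99 lower, of which 112 were also called in sedentary mice, all 112 in the same direction. The lowest adjusted p values belonged to Lpgat1, a phospholipid acyltransferase gene (1.30, SE 0.13, adjusted p = 2.4e-07), the RNA-binding protein gene Fmr1 (1.51, SE 0.17), the glycerol phosphate shuttle gene Gpd2 (−1.78, SE 0.20), Prelp (1.37, SE 0.15) and the immunoglobulin gene Ighm (3.23, SE 0.27). Fatty acid synthesis genes had 14 of 22 lower (18 adjusted over the list alone, median −1.08, adjusted p = 0.0115 with an estimated correlation). The nuclear respiratory chain had 8 of 74 lower (32 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation), and macrophage markers had 0 of 17 called (median 0.63, adjusted p = 0.439 with an estimated correlation). The count was 143 within the single run and 117 without HFD trained replicate 2. The interaction called 1 gene, the matrix protein gene Dpt (chromosome 1, 164796644 to 164824266; 1.24, SE 0.21, adjusted p = 0.0116), with 484 genes at an unadjusted p under 0.05, 15 by DESeq2 and 1 by voom. Adjusting for the run, Dpt kept its call (1.21, adjusted p = 0.0122), but within the single run it did not (1.29, adjusted p = 0.239), and the 1 gene called there was another. Dpt was at 189 ± 40 CPM in sedentary and 109 ± 12.2 in trained chow mice, and at 172 ± 27.5 and 231 ± 37.5 in sedentary and trained HFD mice. The interaction count was 2 without chow sedentary replicate 3, 8 without chow trained replicate 1, 11 without HFD sedentary replicate 2 and 4 without HFD trained replicate 3.

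**Figure D3:**
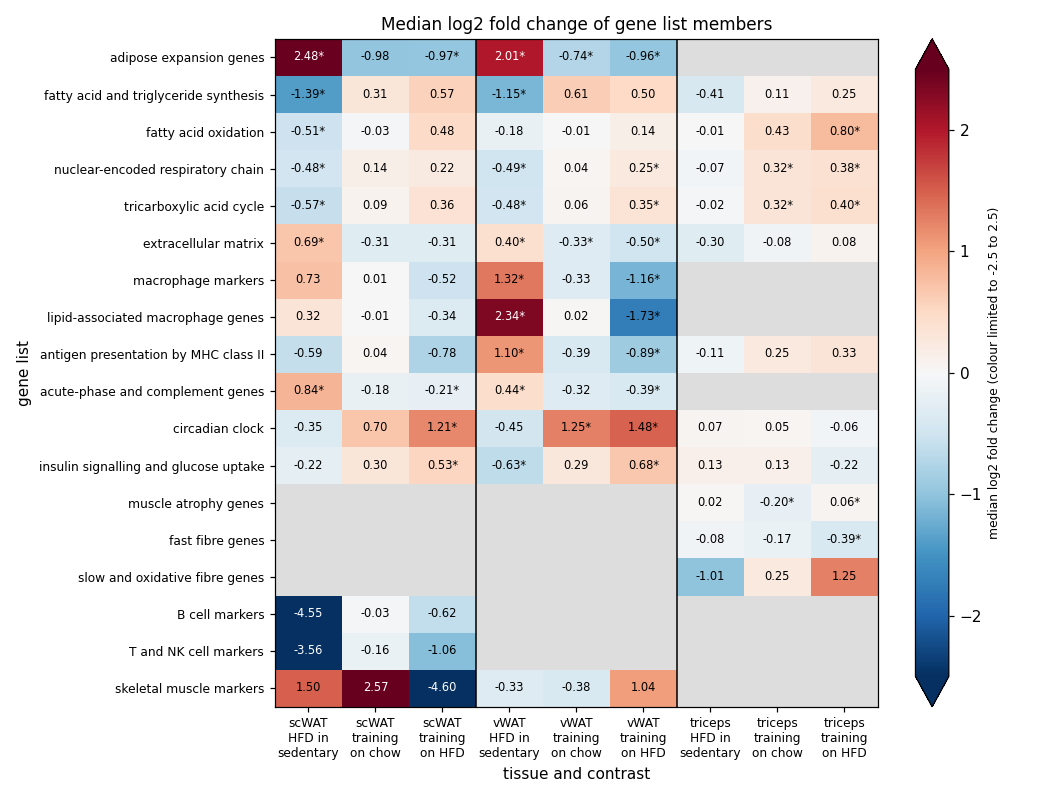
Median log2 fold change of 18 gene lists in the 3 main contrasts of each tissue, coloured from lower to higher, with a star where fry gave an adjusted p under 0.05 and grey where a list was not tested. The clock list has medians of 1.21 and 1.48 under training on HFD in scWAT and vWAT and of −0.06 in triceps, and fatty acid synthesis is at −1.39 and −1.15 under HFD.

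In triceps the diet called no gene in sedentary mice by edgeR, with 198 of 4410 at an unadjusted p under 0.05 and 0 by DESeq2 and by voom. The watched genes of fuel use and fibre type all had an adjusted p of 0.975, with the fast myosin gene Myh4 at 0.14 (SE 0.22), the pyruvate dehydrogenase kinase gene Pdk4 at −0.14 (SE 0.20) and Ucp3 at −0.43 (SE 0.20). Slow fibre genes had a median of −1.01 with 0 of 14 called (camera adjusted p = 1.88e-05, 0.712 with an estimated correlation). In trained mice the diet also called 0 genes, with 308 at an unadjusted p under 0.05 and 0 by DESeq2 and by voom. The interaction was at 0 by all 3 tools, with 226 at an unadjusted p under 0.05.

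Training on chow lowered the ubiquitin ligase genes Fbxo32 and Asb2 in triceps. Fbxo32, the ubiquitin ligase atrogin-1 (chromosome 15, 58175879 to 58214932), fell by 1.43 (SE 0.23, adjusted p = 0.00323), from 216 ± 61.4 to 73.3 ± 19.7 CPM (SD, n = 5). Asb2, part of another ubiquitin ligase, fell by 1.05 (SE 0.19, adjusted p = 0.00205), from 131 ± 27.7 to 57.4 ± 16.7 CPM. Trim63 (−1.19, SE 0.25, adjusted p = 0.0159), Pdk4 (−0.96, SE 0.21, adjusted p = 0.0334) and the mitochondrial creatine kinase gene Ckmt2 (1.04, SE 0.21, adjusted p = 0.0255) passed too, but not in every fit that left out 1 library. Trim63 lost its call without chow sedentary replicate 4 or chow trained replicate 3 or 4 (adjusted p up to 0.0604). Ckmt2 lost it without chow sedentary replicate 1, 4 or 5 or chow trained replicate 1, 3 or 4 (up to 0.0895), and Pdk4 without chow sedentary replicate 1, 4 or 5 or chow trained replicate 1, 2, 4 or 5 (up to 0.0954). Myh4 (−0.47, adjusted p = 0.457), Myh2 (0.97, adjusted p = 0.552) and Ppargc1a (0.30, adjusted p = 0.626) did not pass.

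This comparison called 33 genes, 20 higher and 13 lower, with 476 at an unadjusted p under 0.05. DESeq2 called 99 genes, 71 higher and 28 lower, and voom 65, 39 higher and 26 lower. With only the compared groups fitted, 95 were called, 75 higher and 20 lower. Atrophy genes had 2 of 10 lower (1 higher and 2 lower adjusted over the list alone, median −0.20, camera adjusted p = 0.00706, 0.0388 with an estimated correlation). The nuclear respiratory chain had 5 of 74 higher (43 adjusted over the list alone, median 0.32, camera adjusted p = 6.03e-34, 0.146 with an estimated correlation) and the TCA cycle 2 of 20 higher (14 adjusted over the list alone, median 0.32, 0.0388 with an estimated correlation). Endothelial markers had 0 of 7 called (1 higher adjusted over the list alone, median 0.59, camera adjusted p = 0.000133, 0.0388 with an estimated correlation), a set that moved the same way as the oxidative genes. Fatty acid oxidation had 2 of 23 lower and none higher over all genes, but 11 higher and 3 lower adjusted over the list alone (median 0.43, camera adjusted p = 0.000133, 0.535 with an estimated correlation). A factor for the run gave 44 genes, and the run that held all 4 groups gave 24, where Fbxo32 was at −1.30 (adjusted p = 0.224) and Asb2 at −0.98 (adjusted p = 0.0786). The count was 19, 67, 20 and 14 without chow sedentary replicates 1, 3, 4 and 5, and 16 and 19 without chow trained replicates 1 and 4.

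Genes changed by training on HFD in triceps included enzymes of oxidative fuel use and fast myosins, which went in both directions. Hadhb, of mitochondrial beta-oxidation (chromosome 5, 30155248 to 30184593), rose by 1.00 (SE 0.16, adjusted p = 0.000359), from 295 ± 52.8 to 520 ± 89.6 CPM (SD, n = 5), and Ckmt2 rose by 1.40 (SE 0.21, adjusted p = 0.000855), from 1420 ± 383 to 3300 ± 625 CPM. Myh1, the myosin of fast IIx fibres, rose by 1.91 (SE 0.34, adjusted p = 0.00319), from 644 ± 351 to 2130 ± 353 CPM. Myh4, the myosin of the most glycolytic IIb fibres, fell by 0.95 (SE 0.22, adjusted p = 0.0156), from 16200 ± 4260 to 7370 ± 2840 CPM, but not without HFD sedentary replicate 1 (−0.85, adjusted p = 0.0567). The calcium buffer gene Pvalb fell by 0.85 (SE 0.14, adjusted p = 0.000289). Pdk4 (chromosome 6, 5483351 to 5496309), which blocks glucose oxidation, fell by 1.32 (SE 0.21, adjusted p = 0.000908), and Fbxo32 fell by 1.25 (SE 0.22, adjusted p = 0.00164), Trim63 fell by 1.34 (SE 0.25, adjusted p = 0.00135) and Asb2 fell by 1.17 (SE 0.18, adjusted p = 0.000104). Angptl4 fell by 2.18 (SE 0.38, adjusted p = 0.000359) and the stress factor Atf4 fell by 0.80 (SE 0.17, adjusted p = 0.00303). Myh2 (1.68, SE 0.55, adjusted p = 0.0976) and Ppargc1a (0.37, adjusted p = 0.31) did not pass.

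Here 236 genes were called, 147 higher and 89 lower, with 838 at an unadjusted p under 0.05. Mitochondrial genes took 23.86 to 33.56% of counts in HFD sedentary and 35.79 to 43.17% in HFD trained libraries. On chow they took 27.17 to 31.17% and 32.31 to 41.56%. The CPM of other genes on total counts is lowered by such a larger share. The nuclear respiratory chain had 32 of 74 higher (55 adjusted over the list alone, median 0.38, camera adjusted p = 2.7e-28, 0.243 with an estimated correlation). Fatty acid oxidation had 13 of 23 higher and 3 lower (20 and 3 adjusted over the list alone, median 0.80, camera adjusted p = 1.32e-12, 0.243 with an estimated correlation), and the TCA cycle 9 of 20 higher (18 adjusted over the list alone, median 0.40, camera adjusted p = 3.89e-15, 0.0938 with an estimated correlation). Fast fibre genes had 1 of 12 higher and 6 lower (1 and 9 adjusted over the list alone, median −0.39, camera adjusted p = 2.38e-06, 0.243 with an estimated correlation), and slow fibre genes 1 of 14 higher (3 adjusted over the list alone, median 1.25, camera adjusted p = 2.38e-06, 0.452 with an estimated correlation). Of the 10 atrophy genes 2 were lower, and the list's summaries differed in sign, with a median of 0.06 and a mean of −0.19 (camera adjusted p = 0.437, fry adjusted p = 0.0334).

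With the run as a factor 267 genes were called and within the run that held all 4 groups 309. The medians within that run were 0.55 for the respiratory chain, 1.03 for fatty acid oxidation, 0.53 for the TCA cycle, −0.51 for fast fibre genes and 2.02 for slow fibre genes. Hadhb, Ckmt2, Myh1, Myh4, Pvalb, Pdk4, Fbxo32, Trim63, Asb2, Angptl4 and Atf4 were called in both fits. The count was 132 and 138 without HFD sedentary replicates 1 and 3, and 121 and 149 without HFD trained replicates 2 and 3.

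Whether the diet acted differently on the fat depots was tested within animals. The difference passed for 128 of 7931 genes, 81 with a more positive effect in scWAT and 47 with a more negative one, and 1034 had an unadjusted p under 0.05. Retn differed by 1.55 (SE 0.24, adjusted p = 0.00111, n = 5 mice per group), with 0.22 in scWAT and −1.19 in vWAT. Efemp1 differed by 2.07 (SE 0.32), with 2.17 and 0.13, and Cavin3, of caveolae, by 1.83 (SE 0.29), with 1.95 and 0.21. Lctl differed by −2.22 (SE 0.35), with −0.98 and 1.42, and the flavin monooxygenase gene Fmo1 by 1.32 (SE 0.21, adjusted p = 0.00119), with 0.09 and −1.27. Without the 6 animals whose scWAT held lymph node transcripts 3 genes passed, 1 of them among the 128, with only 2 sedentary chow mice left. In that fit Lctl kept its call (−2.36, adjusted p = 0.00414), and Retn (1.35, adjusted p = 0.0878), Cavin3 (1.44, adjusted p = 0.273), Efemp1 (1.54, adjusted p = 0.422) and Fmo1 (1.23, adjusted p = 0.128) did not. Without the animal as a block Lctl did not pass (−2.40, adjusted p = 0.0512). Leaving out single animals gave 215, 32, 46 and 62 genes without sedentary chow mice SC3, SC4, SC11 and SC12, and 60, 84 and 50 without sedentary HFD mice SH3, SH7 and SH12. The depot difference in the training effect passed for 0 genes on chow, with 305 at an unadjusted p under 0.05, and 0 on HFD, with 343; DESeq2 also gave 0 and 0. On HFD it was 1 without mouse SH4 and 3 without mouse SH12.

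The design also asked whether running moved genes against the diet. Of the 564 genes that the diet changed in sedentary visceral fat, 555 (98.4%) moved the opposite way with training on HFD, and 153 were called in both with opposite signs against 1 with the same sign. In subcutaneous fat 398 of 449 (88.6%) moved the opposite way, with 37 called in both with opposite signs and 1 with the same sign. Both effects share the sedentary HFD mice, which alone makes them oppose each other. When that group was divided so that no library served both effects, the shares averaged 93.7% in vWAT (77.6 to 99.0) and 82.3% in scWAT (67.9 to 89.7) over 20 splits. The mean number of genes called in both with opposite signs was then 29.1 in vWAT and 5.2 in scWAT. In vWAT 19.7 of these rose with diet and fell with training, against 1.0 for independent lists, and 9.4 went the other way, against 0.5. In scWAT these numbers were 4.8 against 0.2 and 0.4 against 0.1.

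Across all genes, which are not independent replicates, 74.2% moved the opposite way in vWAT, 66.1% in scWAT and 64.0% in triceps, against 66.7, 66.5 and 66.9% in simulated sets without any change. The correlation between the effects was −0.635 in vWAT, −0.345 in scWAT and −0.261 in triceps, against −0.491, −0.492 and −0.507 in the simulated sets. The covariance was −0.157 in vWAT, −0.151 in scWAT and −0.0464 in triceps, against −0.0564, −0.0746 and −0.0421. With the sedentary HFD group divided, the mean correlation was −0.327 in vWAT (−0.409 to −0.084), −0.11 in scWAT (−0.325 to 0.19) and −0.059 in triceps (−0.167 to 0.109), so the range held 0 in scWAT and triceps. In triceps, where the diet called no gene, 52.2% of all genes then moved the opposite way. The share of called genes in scWAT was 92.8, 94.1, 93.4 and 93.0% without HFD sedentary replicates 1, 2, 3 and 4, and that of all genes in triceps was 68.7 and 68.4% without replicates 4 and 5.

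Training on chow and on HFD was compared gene by gene. In triceps 29 genes were called under both diets, all 29 in the same direction, with 16 higher against 0.7 by chance and 13 lower against 0.3, and the correlation across genes was 0.426, and 0.338 within the run that held all 4 groups. In vWAT 16 genes were called under both diets, all 16 in the same direction (9 higher against 0.2 by chance and 7 lower against 0.4), with a correlation of 0.188, and 0.082 within that run. In scWAT the correlation was −0.283, with 0.251 in the run of 9 libraries and −0.597 in the run of 11. Over all scWAT libraries, the medians of skeletal muscle markers had opposite signs in these contrasts, higher on chow and lower on HFD. Their summed reads reached 19207 in the run of 9 and 72603 in the run of 11. How far muscle in the pieces of fat sets this correlation was not tested. Of the 71 genes called on HFD, 57 had the same sign on chow. For the diet effect, sedentary and trained mice correlated at 0.513 in scWAT, 0.585 in vWAT and 0.606 in triceps, but in vWAT and triceps chow and HFD libraries differed in library run in both activity groups, and in scWAT, where diets were spread over both runs, 3 of 5 libraries in each chow group held lymph node transcripts. Within the run that held all 4 groups the correlation was 0.253 in vWAT and −0.093 in triceps, so in triceps it did not hold. In scWAT it was 0.749 in the run of 9 libraries, 0.047 in the run of 11 and 0.274 without the 6 lymph node libraries. Without the filter on low counts the diet correlations were 0.220 in scWAT, 0.226 in vWAT and 0.166 in triceps.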

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

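The runs of libraries, the test of a diet effect on organ transcripts and both tests on lymph node transcripts were chosen only after the results they concern had been seen. The first set of scWAT libraries with lymphocyte transcripts had counted Ighm, which marked 18 of 20 libraries, so Ighm was left out of the definition. The test of carryover for these libraries first asked for a 10-fold gap in B cell counts, which the observed gap of 9.48 missed, and it was then rewritten on the stroma genes.

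Single libraries stood apart from the other 4 of their group by Dixon's test in 22 of 140 tests, each of 1 measure in 1 group. Its rate by chance of about 1 in 20 holds for normally distributed values, which low read counts and CPM need not be. A library with 1 read in a group otherwise without reads stands apart by construction. The 22 can therefore not be set against chance. Reads of skeletal muscle genes were at 19207 in scWAT chow sedentary replicate 1 (nearest 1956), at 47451 in scWAT HFD sedentary replicate 4 (nearest 8144) and at 2207 in vWAT HFD sedentary replicate 5 (nearest 127), where the other 2 vWAT libraries of its run, both HFD trained, held 1908 and 2975. Reads of B cell genes stood apart at 31 in scWAT HFD sedentary replicate 5 and at 20 in vWAT HFD trained replicate 3. Reads of genes of the male reproductive tract stood apart at 1724 in vWAT chow trained replicate 3 (nearest 25) and at 111 in vWAT HFD sedentary replicate 4 (nearest 12). The same list gave such libraries at 1 read in 4 scWAT groups, and at 1, 2 and 6 reads in 3 triceps groups, which are counts too low to read.

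Among watched genes, scWAT chow trained replicate 1 stood apart for Fasn at 2610 CPM and Scd1 at 39400 CPM, replicate 2 of that group for Ucp1 at 860 CPM and replicate 3 for Ppargc1a at 34.9 CPM. That replicate 3 also held 72603 reads of skeletal muscle genes, the most of any scWAT library. Itgax was at 5.94 CPM in scWAT chow sedentary replicate 2, equal to the limit for a count of 0 in that library. The slow myosin gene Myh7 was at 33.2 CPM in triceps chow sedentary replicate 3 and, separately, in chow trained replicate 5, and at 19.3 CPM in HFD sedentary replicate 4. No explanation was tested for these gene values.

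Effects differed between groups by a test of the difference itself in these cases. The training effect on Dpt in vWAT differed between diets by 1.24 on the log2 scale, but was not called within the run that held all 4 groups (1.29, adjusted p = 0.239). The diet effect in sedentary mice differed between the depots for 128 genes, led by Retn at 1.55, Lctl at −2.22, Cavin3 at 1.83, Efemp1 at 2.07 and Fmo1 at 1.32. Without the 6 animals with lymph node transcripts, 4 of these 5 genes lost their call and only Lctl kept it. All 5 kept their direction in that fit, which had only 2 sedentary chow mice left.

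The first pattern weighed is that of heart, intestinal and brain transcripts in runs of libraries with neighbouring codes; liver reads followed the runs in scWAT and triceps but not in vWAT. If RNA or reads carried over between libraries pooled together, the 5 triceps libraries that share a run with 3 vWAT libraries should hold more reads of adipocyte genes, and they held 1.33 times as many as the other 15 (853.8 ± 152 against 643.3 ± 147.7, exact permutation test, p = 0.0138 over 15504 arrangements). A diet effect on intestinal genes is argued against, since the highest count outside the run was 1.75% of the lowest inside. In the other direction, the 3 vWAT libraries of that run held 1908 to 2975 reads of skeletal muscle genes, against 83 to 465 in the other 17, which was seen afterwards and not tested. Carryover within pools of 12 is therefore a candidate explanation, and fat left on the muscle remains open for the adipocyte reads, since all 5 libraries are from chow mice and the 5 chow triceps libraries outside the run held 444 to 796 such reads, against 678 to 1094 inside it.

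The second pattern is that of lymphocyte transcripts in 6 of 10 chow and 0 of 10 HFD scWAT libraries. Carryover is argued against, since within each run the lowest count of the stroma genes in a library with these transcripts was at least 25.2 times the highest in the other libraries. Lymph node tissue in the pieces of fat may be the source, since the stroma genes had at least 403 reads in every one of the 6 libraries and at most 19 in the other 14. Whether diet changed the size of the node, or the share of the dissected piece that it filled, remains open.

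The third pattern is the fall of mitochondrially encoded transcripts in vWAT of sedentary HFD mice. Heart RNA is rich in these transcripts and was found in 5 chow libraries, but the median change within the run that held all 4 groups was −1.01 (SD 0.32 across 17 genes), which that explanation forbids. The highest heart share was 0.148% of a vWAT library, and the median also fell in scWAT (−0.92), where heart reads were at most 120. A lower mitochondrial content or transcription in these adipocytes, or a larger share of other cell types, stays open as untested.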

How the results depend on the processing

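Tests with the library run as a factor, within runs, without the 6 lymph node libraries or animals, and with B cell and muscle scores as covariates were chosen after the data had been seen. Where a change has no cause named here, the cause was not tested.

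Of the 313 named gene values, 298 kept their side of the threshold and their direction with DESeq2, 312 with RLE normalisation and 296 without the filter. Of 308 values, 286 did with limma voom, 286 with the run as a factor and 302 with the replicate block, and no called gene reversed in any of these fits. Within the run that held all 4 groups 114 of 201 did, and 87 of the 170 called values lost their call. Without the 6 lymph node libraries 76 of 102 did, and 26 of the 85 called values lost their call. In scWAT, 90 of 90 called values lost their call in the first run alone and 35 of 90 in the second run alone. All of these fits rest on fewer libraries. Of 240 list results, 159 were the same with an estimated correlation, where 81 of 105 calls were lost.

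Without the filter more genes were tested, and counts rose in scWAT to 724 for diet in sedentary mice, 30 and 199 for training on chow and HFD, 747 for diet in trained mice and 58 for the interaction. In vWAT they were 83 and 357 for training and 34 for the interaction, in triceps 24 and 2 for diet in sedentary and trained mice and 61 for training on chow, and for the depot difference 467, 33 and 113. DESeq2 gave 2 and 136 genes for training on chow and HFD in scWAT, 618 for diet in trained mice and 31 for the interaction, 66 for training on chow and 15 for the interaction in vWAT, and 99 for training on chow in triceps. Voom gave 109 for training on HFD in scWAT and 65 for training on chow in triceps. With only the compared groups fitted, training on HFD gave 129 in scWAT and training on chow gave 95 in triceps.

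By the criterion that every same-numbered pair correlate above 0.1, replicate numbers were not taken as pairs within a tissue. Over 30 such pairs per tissue, the mean correlation of deviations was 0.149 in scWAT (−0.187 to 0.559, 16 above 0.1), 0.043 in vWAT (−0.204 to 0.277, 11 above) and 0.009 in triceps (−0.262 to 0.19, 7 above), against −0.037, −0.011 and −0.002 for other pairs. In scWAT, vWAT and triceps, 7, 4 and 3 of 20 libraries correlated best with their own number. A partial likeness of same-numbered libraries would also fail the criterion for every pair, and in scWAT the mean of 0.149 leaves it open. In scWAT, replicates 1 and 2 of every group lay in the first run of codes. With a replicate block, scWAT had 646 genes for diet in sedentary mice, 2 for training on chow and 552 for diet in trained mice, vWAT had 8 for the interaction and triceps had 1 for diet in sedentary mice. Without the animal as a block the depot difference under HFD had 71 genes.

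With the run as a factor, training on chow in scWAT had 1 gene, and in vWAT diet had 294, training on HFD 334 and the interaction 11. The first run of scWAT alone gave 0 for diet in sedentary mice, for training on HFD and for diet in trained mice, and the second run gave 267, 22 and 235. The balanced run of vWAT gave 87 for diet and 6 and 66 for training on chow and HFD. Without the lymph node libraries scWAT had 139, 109 for training on HFD and 149 for diet in trained mice, and with the covariates 9 for training on chow, 183 for diet in trained mice and 5 for the interaction. Without the animals concerned the depot difference had 3 genes for diet and 2 for training on HFD. The median of the 16 mitochondrially encoded genes in scWAT under diet, at −0.92, was −0.92 without the lymph node libraries, −1.18 in the first run and −0.89 in the second, with 6, 0 and 4 of them called lower against 10.

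Some list medians changed direction in these added fits. In scWAT under diet, MHC class II (−0.59 with all libraries) was at 0.89 without the lymph node libraries and 0.64 with covariates, and skeletal muscle at −1.78 in the first run, 0.33 without the lymph node libraries and −0.24 with covariates. For training on chow in scWAT the first run gave 0.72 for thermogenic genes, −0.15 for interferon genes and −1.05 for muscle, the second run −0.024 for the respiratory chain, 0.12 for the matrix and −0.48 for B cells, and the fit without lymph node libraries −0.38 for interferon genes and −0.73 for proliferation. Proliferation in vWAT on chow was at 0.58 within the balanced run. In triceps under diet, adipocyte genes were at 0.10 with the run as a factor and 0.01 within the balanced run, and the respiratory chain at 0.015 and −0.005.

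Leaving out 1 library at a time gave the following lowest and highest counts. In scWAT they were 243 and 644 for diet in sedentary mice, 0 and 5 for training on chow, 28 and 88 for training on HFD, 200 and 610 for diet in trained mice and 0 and 1 for the interaction. In vWAT they were 355 and 629, 20 and 51, 84 and 340, 117 and 182, and 1 and 11, in the same order. In triceps they were 0 and 0, 14 and 67, 121 and 293, 0 and 0, and 0 and 0. The depot difference had 32 and 215 for diet, 0 and 0 for training on chow and 0 and 3 for training on HFD. The share of genes with opposite changes lay between 91.1 and 94.1% in scWAT, 98.0 and 98.6% in vWAT and 61.7 and 68.7% in triceps. With the sedentary HFD group divided it was 82.3% in scWAT, 93.7% in vWAT and 52.2% in triceps, and over all genes 66.1% in scWAT and 74.2% in vWAT, against 66.5 and 66.7% simulated without any change. The correlations between effects without the filter were 0.220 for diet in scWAT, −0.047 for training, 0.226 and 0.011 in vWAT, and 0.166 and 0.048 in triceps. In the first run of scWAT they were 0.749 and, with the sign reversed, 0.251, in the second run 0.047 and −0.597, and without the lymph node libraries 0.274 and −0.14. In the balanced run they were 0.253 and 0.082 in vWAT, and −0.093, again reversed, and 0.338 in triceps.

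On simulated data at 5 mice per group, a log2 change of 1 was recovered for 45.3% of genes in scWAT, 52.5% in vWAT and 70.7% in triceps, so changes of that size were often missed. Smaller changes and other depths were not simulated.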

Other observations

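Tests on scrambled groups were set up before the result was seen; the selection of genes in the next paragraph followed the rule for named genes but was made from their values.

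Several called genes were not named in the comparisons above. In vWAT of sedentary HFD mice, the asparagine synthetase gene Asns was at −0.90 and the secretory stress factor gene Manf at 0.83, and with the run as a factor neither was called (−0.74 and 0.57, adjusted p = 0.0867 and 0.2). The list of unfolded protein and integrated stress response genes had 2 of 11 higher and 1 lower (2 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.41). In scWAT the prostaglandin E synthase gene Ptges changed by −2.06 (SE 0.27), the sorting receptor gene Sorl1 by −2.35 (SE 0.32) and the kinase gene Pdk1 by −2.11 (SE 0.26) under the diet, while the metal-binding protein gene Mt2 rose by 1.70 (SE 0.27), and all 4 kept their calls without the 6 lymph node libraries. In triceps on HFD, training lowered the malic enzyme gene Me1 (−1.03, SE 0.21), which supplies NADPH for fat synthesis, and raised Mdh1 (1.11, SE 0.21) and Ephx2 (1.18), and all 3 were called with the run as a factor.

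The clock list was higher with training in both fat depots on HFD, though not every member was called. Its medians in triceps were 0.05 on chow and −0.06 on HFD, with 1 of 8 members called on HFD. Dbp also rose in triceps on HFD, with 5.54 to 12.8 CPM in sedentary and 13.8 to 28.2 CPM in trained mice. It was called there, but lost its call in 6 of 10 fits that left out 1 library. On chow, Dbp in triceps was at 6.86 to 14.6 CPM in sedentary and 2.80 to 28.8 CPM in trained mice. All tissues came from the same animals, and the wheels had been locked for 24 hours. The labels give no time of day for single mice. The difference between tissues in this list was not tested.

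Other splits of the same libraries were counted for each comparison, 100 per comparison, with the real one included. In scWAT the diet effect in sedentary mice (449 genes, highest other 129), the training effect on HFD (71, highest other 2) and the diet effect in trained mice (365, highest other 1) were each reached by 1 split of 100, the real one. Chance is thus unusual for these counts, but 100 splits cannot exclude it. The same holds in vWAT for diet in sedentary mice (564, highest other 130; 1 split), training on HFD (216, highest other 179; 1 split) and diet in trained mice (183, highest other 71; 1 split). For training on chow in vWAT the count of 41 was reached by 2 splits of 100, and the other one called 67 genes, so chance is unusual there but a larger count did arise. In triceps only the real split, 1 of 100, reached the counts for training on chow (33, highest other 25) and training on HFD (236, highest other 167). For the interaction in vWAT, 1 gene was reached by 10 splits of 100 and the highest other gave 24, so chance is not unusual there. Where no gene was called, 100 of 100 splits reach the count by construction, so they say nothing about chance. The highest others there were 704 for training on chow and 208 for the interaction in scWAT, and 10, 4 and 203 for diet in sedentary mice, diet in trained mice and the interaction in triceps.

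For the depot difference 30 splits of the animals were drawn. The diet effect with 128 genes was reached by 1 split, the real one, and the highest other gave 10. Chance is thus unusual there, but 30 splits cannot exclude it. For training, 30 of 30 splits reached the count of 0 by construction, and the highest others gave 219 genes on chow and 8 on HFD. Splits that call many genes where the real one called 0, such as that with 704 genes for training on chow in scWAT, point to some structure of the samples, which was not examined. A candidate source is the lymph node tissue in 6 of the 10 chow scWAT libraries, whose stroma genes had at least 403 reads. Another is skeletal muscle, whose summed reads in these 10 libraries ranged from 131 to 72603. Neither was tested, and which libraries each split joined was not looked at.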
